A study of Arabidopsis thaliana with 28 samples.

How the data were processed

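Whole Arabidopsis thaliana Col-0 seedlings were grown in the dark for 3 days on nylon mesh in hydroponic medium. They were then given 10 µM abscisic acid (ABA) or an ethanol mock for 1, 4, 8, 12, 24, 36 or 60 h, with 2 libraries per treatment and time, 28 in all. Poly(A) RNA libraries were sequenced on an Illumina instrument after a stranded kit. Per the submitters' processing notes the tools were HTSeq 0.5.4 and edgeR 3.6.2 with build TAIR10, without their order or options. The aligner was not stated, and neither was whether counting used the strand, so genes that overlap on opposite strands, and paralogs with near-identical sequence, carry uncertain values.

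The deposited table gave RPKM, reads scaled by gene length and library size, for 18310 genes in 28 libraries, per the file headers. It also gave the authors' log2 fold change of ABA against mock at each time, and the authors' FDR of the same comparison, an adjusted p-value. The authors had kept genes above a low-count limit in at least 2 libraries, so weakly expressed genes were absent before any step taken here, and the absence of a gene from the table says nothing about its change. In each line of the deposited table a space separated the gene identifier from the first RPKM value, and the field was split there. Of 512680 RPKM values, 100.0% were whole multiples of a gene's and a library's step within 0.01 reads, and reads were recovered from them. These numbered 16.27 to 26.6 M per library, with a median of 20.55 M. They count reads in the kept genes only. The authors' scaling factor, relative to reads, lay between 0.922 and 1.125. At a gene of median length, 1 read stood for 0.0229 to 0.041 RPKM. Intervals and floors given for read counts (95%, exact binomial) cover counting error only. Names and positions were taken from a reference annotation of build TAIR10.1, whose chromosome sequences carry the coordinates of TAIR10, the build that the notes name; 89 genes had no match by name there. Starts and ends are those of the reference annotation and may differ from the gene models that the authors counted on.

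Values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, in a single model with a mean for each of the 14 groups and an intensity trend for the prior variance, two-sided. The residual degrees of freedom were 14, or 17.7 with the prior. Adding 1 before the logarithm makes differences of weakly expressed genes smaller than their true ratio. P-values were adjusted by the Benjamini-Hochberg procedure over the 18310 genes, and a gene was called at an adjusted p under 0.05. The median standard error of a log2 difference at a single time was 0.19. The contrasts were ABA minus mock at each of the 7 times, their mean, the ABA effect at 60 h minus that at 4 h and at 4 h minus that at 1 h, and moderated F tests for any ABA effect, for an ABA effect that differs between times, and for a change of the mock seedlings over time. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples only.

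Whether replicate number pairs an ABA with a mock library was checked from residuals. At the 7 times, the deviation of the first replicate from the second correlated between ABA and mock across genes with Pearson's r of 0.43 to 0.74. Genes are not independent replicates, so no p is given. Libraries that share a number at a time thus share structure. A model with a block for each pair left 7 residual degrees of freedom (11.7 with the prior) and a median standard error of 0.12, and called about as many genes again. The unpaired counts are the ones reported, as planned, and the paired counts stand beside those of the times, the contrasts and the lists described. Deviations also correlated within 1 to 12 h (median r 0.47) and within 24 to 60 h (0.71), and less between these spans (0.28).

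The genes to name were set by rule. The rule took the 5 largest increases and 5 largest decreases at each time among called genes whose ABA libraries both lay beyond both mock libraries, an arrangement that chance gives in 33.3% of unchanged genes. It took the 10 largest in each direction for the mean over times among genes of constant sign, the 5 smallest p of the F test for a time-dependent effect, and the 3 largest 60 h minus 4 h differences in each direction. Members of fixed gene lists could be named as well, and so could the genes of the mock time course with the smallest p. Of 31 lists with 425 loci, 384 loci were measured. One list, salicylate and ethylene defence markers, was not tested, because none of its 4 loci remained in the table, and 30 lists were tested. The tested lists covered ABA receptors, clade A PP2C phosphatases, SnRK2 kinases, ABF and ABI5 bZIP factors, other ABA-related transcription factors, ABA effectors and feedback proteins, LEA and dehydrin proteins, seed storage and oil body proteins, ABA biosynthesis, ABA catabolism, conjugation and transport, proline and raffinose metabolism, cuticular wax and lipid transfer, suberin synthesis and export, the Casparian strip, auxin, gibberellin, brassinosteroid, cytokinin and jasmonate genes, cell wall expansion, root hairs, stomata, the cell cycle, light harvesting, chlorophyll synthesis and dark growth, the circadian clock, senescence and sugar starvation, flavonoids, aquaporins and hypoxia. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 210 tests of 30 lists at 7 times. Camera with an estimated correlation and fry were alternatives. Fry's directional p asks whether members move on balance in one direction and its mixed p whether they move in either; neither compares a list with other genes. Groups, contrasts, lists, the naming rule and the alternatives to be run were fixed before the data were examined.

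The alternatives were pseudocounts of 0.1 and 5, a filter at a mean of 1 RPKM (17663 genes), median-ratio scaling, quantile normalization, no intensity trend, a block for replicate number, a block for each pair, only the 4 libraries of a time, a minimum absolute log2 difference of 1, and leaving out each library in turn. The planned tests on counts were not run, a departure from the plan, since whole reads could be recovered and the tools were installed; the instructions for this work keep count tools from tables in RPKM. Precision weights from voom on the recovered reads were added in their place after the data were seen. The model was tested on simulated counts in which genes were changed at 4 h. Each gene's spread was its average over the 14 groups. The model recovered 1.5% of 67 genes changed 1.5-fold, 40.3% of 67 changed 2-fold and 87.9% of 66 changed 4-fold. In the simulation 87 genes were called at 4 h, against 2329 in the data, so its p-value cutoff was stricter. These shares thus describe the simulation and need not hold for the data.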

Results

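Poly(A) RNA was measured in whole Arabidopsis thaliana Col-0 seedlings that had grown for 3 days in darkness and then received 10 µM abscisic acid (ABA) or ethanol as mock. Sampling followed after 1, 4, 8, 12, 24, 36 and 60 h, so there were 14 groups with 2 libraries in each, 28 libraries in all. The table held RPKM values of 18310 genes. Depth, as reads recovered in these genes, ran from 16.27 M (ABA at 60 h, replicate 1) to 26.6 M (mock at 12 h, replicate 1), with a median of 20.55 M. The 10 most abundant genes took 4.28 to 5.4% of reads, and organelle genes took 0.16 to 1.28%. The labels do not say that replicates were separate cultures, so errors describe the spread between these libraries. Effects below are log2 differences of RPKM + 1, ABA minus mock, ± the standard error of the model, with 2 libraries per group at a time. Ranges in brackets after RPKM are SDs of 2 libraries, and positions are on build TAIR10.1.

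Samples followed time on the first component (51.2% of variance) and parted by treatment on the second (26.3%). From 4 h on, the ABA libraries also lay above mock of the same time on the first component. At 24 h they lay at 0.173 and 0.205, against 0.043 and 0.038 in mock. The mock libraries lay at 0.024 or above on the second component and the ABA libraries at -0.072 or below. Component 3 (5.8%) followed the replicate number. Replicates of a group correlated with Pearson's r of 0.975 to 0.99 across genes, yet their reads differed by more than counting error, with a chi-square per degree of freedom of 13.8 to 57.1.

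**Figure D1:**
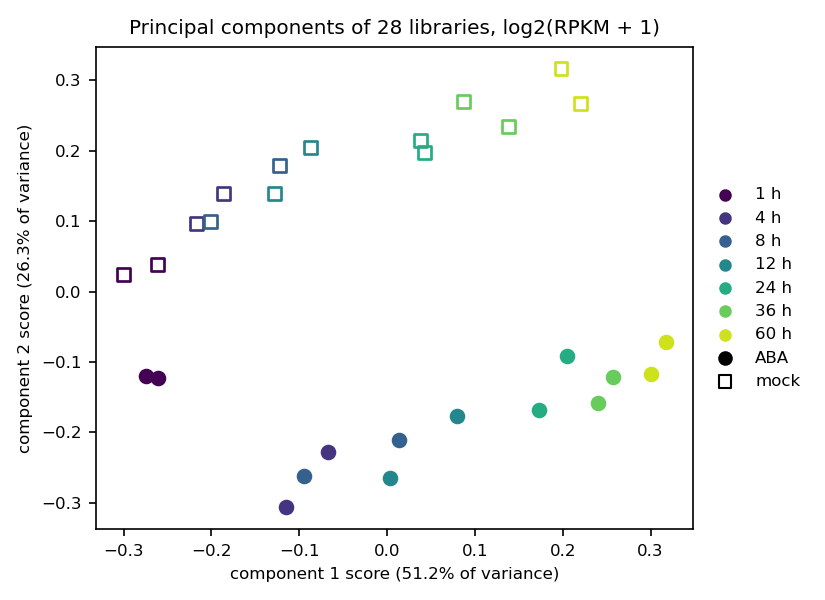
The 28 libraries on the first and second components of log2(RPKM + 1), which hold 51.2% and 26.3% of the variance. Mock libraries lie at 0.024 or above on the second, ABA libraries at -0.072 or below.

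ABA changed few genes at 1 h and many from 4 h on, and most of the changes were increases. At 1 h 383 genes passed (311 higher, 72 lower), at 4 h 2329 (1644 and 685), at 8 h 2104 (1450 and 654) and at 12 h 2281 (1532 and 749). At 24 h 1926 passed (1216 and 710), at 36 h 2531 (1508 and 1023) and at 60 h 2485 (1435 and 1050). The share of increases among them fell from 81.2% to 57.7% between 1 h and 60 h in these counts, without a test of the trend; quantile normalization lowers it by more than 10 points at 4 h and 12 h. A block for each ABA and mock pair gave 901, 4996, 4578, 5208, 4473, 5443 and 5233 genes in order of time, about double. An absolute difference of at least 1 in log2(RPKM + 1) was met by 233, 1111, 1012, 1112, 916, 1182 and 1144 genes. For weakly expressed genes this limit asks for more than a 2-fold change. The median log2 difference over the 18310 genes lay between -0.019 and 0.009.

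**Figure D2:**
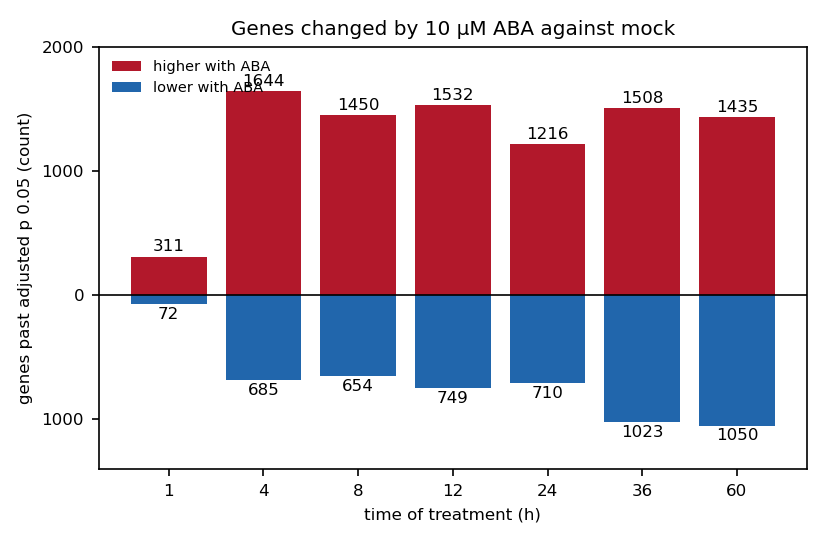
Genes higher and lower with ABA at each time, 311 and 72 at 1 h, 1644 and 685 at 4 h, 1435 and 1050 at 60 h. The share of increases depends on scaling, as at 4 h with 70.6% as deposited and 60.5% after quantile normalization.

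Calls persisted between times. Of 311 genes higher at 1 h, 301 were higher at 4 h as well (27.9 expected if calls were independent), and 65 of 72 lower genes stayed lower (2.7 expected). Between 4 h and 60 h 907 increases (128.8 expected) and 347 decreases (39.3 expected) were shared. All times share 1 estimate of each gene's spread, so calls are not independent and some overlap arises from that alone. In total 4427 genes were called at some time, 2587 higher and 1879 lower, with 39 in both sets. At all 7 times 223 genes were higher and 52 lower, and from 4 h on these numbers were 733 and 234.

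Which genes respond within 1 h? The largest increase among called genes was that of HSFA6B (AT3G22830, chromosome 3, 8078789 to 8081059), a heat-stress transcription factor, by 4.83 ± 0.27, from 0.86 (SD 0.343) to 53.8 (SD 22.3) RPKM (adjusted p = 5.65e-09). GOLS2 (AT1G56600, chromosome 1, 21207537 to 21209635), a galactinol synthase, rose by 4.07 ± 0.36 (64.6 against 2.86 RPKM, adjusted p = 1.59e-06), and the sucrose-phosphate synthase gene SPS2F (AT5G11110) by 3.73 ± 0.15 (84.9 against 5.44). AT1G49450, for a WD40-repeat protein, rose by 3.62 ± 0.33, and AT3G03341 by 3.61 ± 0.4 to 166 RPKM. The ABA receptor gene PYL6 (AT2G40330, chromosome 2, 16844588 to 16846194) fell by 2.04 ± 0.2 (0.85 against 6.48 RPKM, adjusted p = 3.6e-06). AT5G48430, for an aspartyl protease, was lower (-1.98 ± 0.28), and so were AT3G14260 (-1.89 ± 0.23), AT1G52200 (-1.77 ± 0.24) and AT3G13760 (-1.7 ± 0.17), for a DC1-domain protein. For each gene named by size at a time, both ABA libraries lay beyond both mock libraries, which chance gives in 33.3% of unchanged genes. When a library is left out, 211 to 291 genes pass at 1 h.

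At 4 h LTP4 (AT5G59310, chromosome 5, 23924990 to 23925957), a lipid transfer protein gene, rose by 7.7 ± 0.37 (272 against 0.143 RPKM, adjusted p = 5.52e-11), and its neighbour LTP3 (AT5G59320) by 7.31 ± 0.34 (432 against 1.67). PELPK1 (AT5G09530, chromosome 5, 2959734 to 2961382), for a proline-rich cell wall protein, rose by 7.03 ± 0.18 (195 against 0.491, adjusted p = 3.01e-14), PELPK2 (AT5G09520) by 6.61 ± 0.34, and AT2G22510 by 6.35 ± 0.7 (150 against 0.651). Members of the pairs LTP3 and LTP4, and PELPK1 and PELPK2, are alike in sequence, and how the authors' aligner placed reads that match both members is not stated. AT1G29090 (chromosome 1, 10162795 to 10164452), for a papain-type cysteine protease, fell by 4.09 ± 0.24, from 97 (SD 2.55) to 4.78 (SD 0.993) RPKM (adjusted p = 6.14e-10). AT5G46960, for an invertase or pectin methylesterase inhibitor, fell by 3.89 ± 0.4, and AT3G02620 (-3.45 ± 0.56), for an acyl-ACP desaturase, and the class III peroxidase gene AT5G64120 (-3.41 ± 0.58) were lower too. The glutathione S-transferase gene GSTF14 (AT1G49860) fell by 3.37 ± 0.32, with 455 reads in mock and 3 with ABA, a ratio of 143 (95% counting interval 48.5 to 695).

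LTP4, LTP3, PELPK1 and AT2G22510 were among the 5 largest increases at 8 h and 12 h too, while PELPK2 stood at 5.38 and 5.4. LTP4 stood at 8.87 ± 0.37 at 8 h (525 RPKM, and 13450 reads against 3, a ratio of 4500, interval 1540 to 21800) and at 8.7 ± 0.37 at 12 h. LTP3 stood at 8.17 and 7.6, PELPK1 at 6.49 and 6.63, AT2G22510 at 6.81 and 6.93. RD29B (AT5G52300), for a hydrophilic stress protein, rose by 5.87 ± 0.44 at 8 h (1700 against 28.2 RPKM, adjusted p = 2.86e-08), and AT2G37870, a lipid-transfer-like gene, by 5.97 ± 0.38 at 12 h (182 against 1.92). AT1G29090 was at -5.33 ± 0.24 at 8 h and -6.15 ± 0.24 at 12 h (0.42 against 100 RPKM, adjusted p = 1.06e-11). The polygalacturonase gene PGAZAT (AT2G41850, chromosome 2, 17461655 to 17464242) fell by 4.64 ± 0.23 at 8 h (0.414 against 35.3 RPKM, adjusted p = 1.22e-10) and was at -4.72 ± 0.23 at 12 h. AT5G46960 was at -4.49 and -4.59 at these times, the latter with 766 reads in mock and 3 with ABA (ratio 220, interval 75.1 to 1070). AT1G26250, for an extensin-like protein, was at -3.87 ± 0.58 and -4.83 ± 0.58. Decreases also met AT1G45015 at 8 h (-3.48 ± 0.23) and AT4G07820, for a CAP-domain protein, at 12 h (-3.86 ± 0.39).

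At 24 h ENODL1 (AT5G53870, chromosome 5, 21869774 to 21871391), for an early nodulin-like protein, joined the largest increases with 5.86 ± 0.39 (293 against 3.75 RPKM, adjusted p = 1.2e-08). LTP4 stood at 7.96, LTP3 at 7.04, PELPK1 at 5.83 and AT2G22510 at 5.78 ± 0.7. AIR1 (AT4G12550, chromosome 4, 7439115 to 7439805), an auxin-induced root gene of lipid-transfer type, fell by 4.43 ± 0.85 (4.18 against 140 RPKM, adjusted p = 0.00141), with a mock SD of 127. Its neighbour AT4G12545 (chromosome 4, 7434199 to 7434858) fell by 4.18 ± 0.67. Further decreases were AT1G29090 (-5.59 ± 0.24), AT1G26250 (-4.6 ± 0.58) and PGAZAT (-4.51 ± 0.23). With the 4 libraries of 24 h alone 842 genes passed in place of 1926.

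At 36 h and 60 h LEA7 was among the 5 largest increases and AIR1 among the 5 largest decreases. LEA7 (AT1G52690, chromosome 1, 19619724 to 19621534), for a late embryogenesis abundant protein, rose by 5.84 ± 0.55 at 36 h and 6.33 ± 0.55 at 60 h (6790 against 95.6 RPKM, adjusted p = 1.63e-07). KIN1 (AT5G15960) rose by 5.97 ± 0.49 at 60 h (387 against 5.23), and the dehydrin gene RAB18 (AT5G66400, chromosome 5, 26518277 to 26519447) by 5.56 ± 0.42 to 11300 (SD 1890) RPKM from 271 (SD 187, adjusted p = 3.29e-08). LTP4 had 9996 reads against 3 at 36 h (ratio 3300, interval 1130 to 16000) and 5726 against 0 at 60 h, at least 1930-fold against a floor of 3 reads. LTP3 stood at 7.83 and 7.18, and PELPK1 at 6.19 and AT2G22510 at 5.9 at 36 h. AIR1 was at -6.22 ± 0.85 and -6.32 ± 0.85 (0.378 against 136 RPKM at 60 h, adjusted p = 2.78e-05). AT4G12545 was at -5.37 and -5.2 ± 0.67; at 60 h it had 998 reads in mock and 2 with ABA (ratio 493, interval 136 to 4080). Lower at 36 h were AT1G29090 (-4.99), AT1G26250 (-4.97) and AT4G07820 (-4.45 ± 0.39). Lower at 60 h were AT2G28780 (-4.9 ± 0.25), AT1G26250 (-4.68) and the peroxidase gene AT5G64110 (-4.28 ± 0.31). The 4 libraries of a time alone gave 1241 genes at 36 h and 921 at 60 h.

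Averaged over the 7 times, LTP4 and LTP3 rose by 7.23 ± 0.14 and 6.68 ± 0.13, PELPK1 by 5.28 ± 0.07 and AT2G22510 by 5.11 ± 0.27 (14 libraries per treatment). HAI3 (AT2G29380), a PP2C phosphatase gene, rose by 4.98 ± 0.07 (49.9 against 0.41 RPKM, adjusted p = 4.2e-19). RD29B followed with 4.77, LEA7 with 4.69, LTI30 (AT3G50970) with 4.48, AT2G37870 with 4.47 and ENODL1 with 4.41. The largest mean decreases among genes of constant sign were AT1G29090 (-4.38 ± 0.09), AT1G26250 (-3.84), AT2G28780 (-3.28), AT1G45015 (-3.15) and GSTF14 (-3.12). AT5G46960 (-3.06), AT4G07820 (-2.95), AT3G02620 (-2.91), AT3G14260 (-2.85) and AT1G30760 (-2.82 ± 0.07), for a berberine-bridge-type enzyme, came next. In this test 7165 genes passed (39.1%; 10618 with paired blocks), 3851 higher and 3314 lower, and 878 changed at least 2-fold. The balance of directions depends on scaling: increases were 53.7% as deposited, 47.7% after median-ratio scaling and 40.3% after quantile normalization.

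The clade A PP2C genes, negative regulators of ABA signalling, rose: at 4 h HAI3 (chromosome 2, 12608675 to 12610350) by 5.32 ± 0.19 (52.7 against 0.361 RPKM, adjusted p = 1.14e-12), HAI1 (AT5G59220) by 4.82 ± 0.27, PP2CA (AT3G11410) by 3.63 ± 0.19 and ABI2 (AT5G57050) by 3.02 ± 0.17. At 1 h HAI1 was already up by 3.39 ± 0.27 (58.4 against 4.83) and ABI1 (AT4G26080) by 2.1 ± 0.17. All 9 members passed at each of the 7 times, 9 when adjusted over the list alone and 9 with paired blocks, with a median of 3.53 at 4 h (camera adjusted p = 5.11e-23, adjusted p = 0.00112 with an estimated correlation). Among receptor genes at 4 h PYL4 (AT2G38310, chromosome 2, 16049918 to 16051356) fell by 2.53 ± 0.34 (13.2 against 81.2 RPKM, adjusted p = 2.87e-05), and PYL6 (-2.31 ± 0.2) and PYL5 (AT5G05440, -1.62 ± 0.28) were lower with it. PYR1 (-0.9), PYL1 (-0.52), PYL8 (-0.47), PYL7 (0.68) and PYL9 (0.42) did not pass. That made 3 of 8 measured receptors, of 14 listed, and 3 when adjusted over the list alone; paired blocks gave 2 higher and 6 lower (camera adjusted p = 0.00391, adjusted p = 0.057 with an estimated correlation). At 60 h the latter value was 0.0234. For each of 978 calls of list members at single times, both ABA libraries lay beyond both mock libraries. Leave-one-out fits kept 674 of 985 such calls throughout, 7 calls over all libraries included.

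Of the SnRK2 kinase genes SNRK2.7 (AT4G40010) rose by 2.24 ± 0.31 at 4 h, SNRK2.9 (AT2G23030) by 1.21 ± 0.24, SNRK2.10 (AT1G60940) by 0.8 ± 0.11 and SNRK2.6 (AT4G33950) by 0.58 ± 0.16; the last call is lost when any of the 4 libraries is left out and after quantile normalization. SNRK2.2 (0.08) and SNRK2.3 (-0.12) did not pass. In all 4 of 10 passed, 5 when adjusted over the list alone and 5 with paired blocks (camera adjusted p = 0.00642, adjusted p = 0.0729 with an estimated correlation). Among bZIP factors ABF2 (AT1G45249) rose by 2.13 ± 0.2 at 4 h, ABI5 (AT2G36270) by 2.12 ± 0.33, ABF3 (AT4G34000) by 1.76 ± 0.24, ABF4 (AT3G19290) by 1.45 ± 0.17 and ABF1 (AT1G49720) by 1.02, while AREB3 (0.03) and EEL (-0.09) did not pass. These are 5 of 7 measured, 5 when adjusted over the list alone and 5 with paired blocks (camera adjusted p = 1.87e-05, adjusted p = 0.0795 with an estimated correlation). Other ABA-related transcription factors responded at 1 h: NAC019 (AT1G52890) by 3.04 ± 0.25, MYB102 (AT4G21440) by 2.67 ± 0.22, RD26 (AT4G27410) by 2.47 ± 0.15 (82 against 14.2 RPKM, adjusted p = 2.24e-08) and the zinc finger gene ZAT6 (AT5G04340) by 2.43 ± 0.18. HB5 (-0.07), ABR1 (-0.2) and ABI3 (0.68) did not pass. Of 27 measured 21 passed, 24 when adjusted over the list alone and 23 with paired blocks (camera adjusted p = 1.84e-60, adjusted p = 4.44e-05 with an estimated correlation). Effector and feedback genes rose at 4 h in 15 of 16 cases, 16 when adjusted over the list alone and 15 with paired blocks, led by ADH1 (AT1G77120) with 4.53 ± 0.22 (114 against 4 RPKM), AT5G50360 with 4.21 ± 0.29, RD22 (AT5G25610) with 3.55 ± 0.19 and MAPKKK18 (AT1G05100) with 3.4 ± 0.23. HVA22A (0.27) did not pass (camera adjusted p = 4.51e-25, adjusted p = 0.00467 with an estimated correlation).

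**Figure D3:**
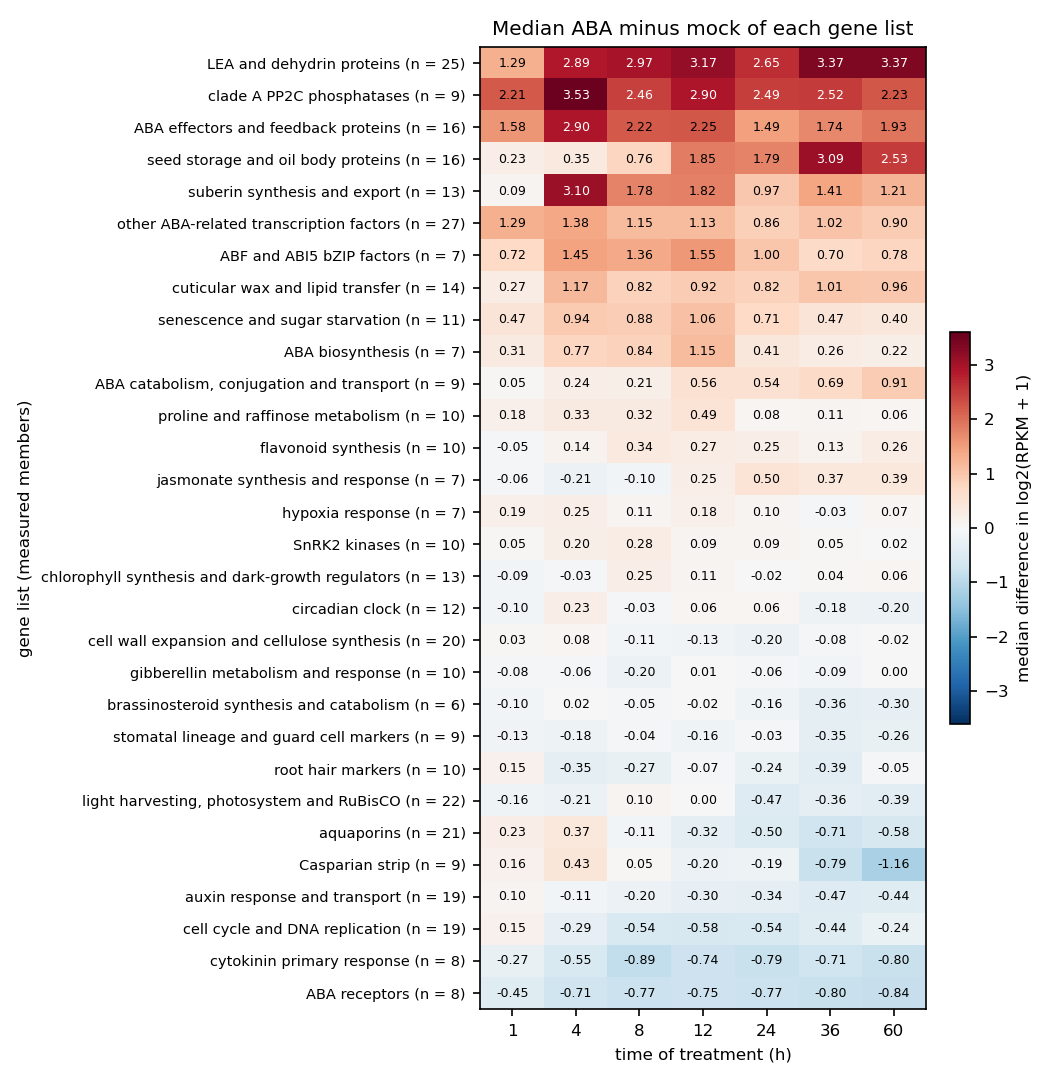
Median log2 difference, ABA minus mock, of the members of 30 lists at 7 times, such as 3.53 for PP2C genes and -0.71 for receptors at 4 h. Of 210 medians 7 differ in sign between scalings, none of these beyond 0.1 in size as deposited; light harvesting genes at 8 h go from 0.1 to -0.16 after quantile normalization.

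Some genes of ABA synthesis and some of ABA breakdown rose, and the order of the 2 lists was not tested. NCED3 (AT3G14440, chromosome 3, 4831286 to 4834015), for the dioxygenase that makes the ABA precursor xanthoxin, was higher by 1.5 ± 0.21 at 1 h (7.95 against 2.14 RPKM, adjusted p = 0.000222) and 1.82 ± 0.21 at 4 h, but at 60 h its difference was -0.07 (adjusted p = 0.924). ABA1 (AT5G67030) rose by 1.26 ± 0.15 at 4 h, AAO3 (AT2G27150) by 1.07 ± 0.23 and ABA3 (AT1G16540) by 0.44 ± 0.12, a call that is lost without any of the 4 libraries; ABA2 (0.08), ABA4 (0.58) and NCED9 (0.77) did not pass. Thus 4 of 7 measured passed at 4 h, 6 when adjusted over the list alone and 6 with paired blocks (camera adjusted p = 0.000118, adjusted p = 0.00653 with an estimated correlation). The ABA 8'-hydroxylase genes rose at 60 h, CYP707A1 (AT4G19230) by 2.43 ± 0.28 (80.5 against 14.4 RPKM, adjusted p = 4.89e-06), CYP707A2 (AT2G29090) by 1.86 ± 0.21 and CYP707A3 (AT5G45340) by 1.6 ± 0.24, and so did the glucosidase gene BG1 (AT1G52400) by 1.37 ± 0.15. UGT71C5 (-0.31) and DTX50 (0.2) did not pass. Of 9 measured 6 were higher and 1 lower, AIT1 (AT1G69850) by -0.55, a call lost in 4 leave-one-out fits and with voom weights; the same numbers held when adjusted over the list alone and with paired blocks (camera adjusted p = 0.0002, adjusted p = 0.00718 with an estimated correlation). In this list 3 were higher at 4 h already, 4 at 12 h and 6 at 24 h. In proline and raffinose metabolism GOLS2 stood at 4.32 ± 0.36 at 4 h, the proline synthesis gene P5CS1 (AT2G39800) at 2.73 ± 0.22, RS4 (AT4G01970) at 1.85 ± 0.42, lost in 2 leave-one-out fits, and RS5 (AT5G40390) at 1.37 ± 0.24. PDH1 (-0.35) and P5CS2 (0) did not pass; 4 of 10 did, and 4 when adjusted over the list alone, and paired blocks gave 4 higher and 2 lower (camera adjusted p = 0.0184, adjusted p = 0.0596 with an estimated correlation).

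Most LEA and dehydrin genes rose at 4 h, and some reached high abundance. RD29B reached 1700 RPKM at 4 h against 27.4 (5.89 ± 0.44, adjusted p = 1.6e-08), LTI30 1120 against 23.8 (5.5 ± 0.4), RD29A (AT5G52310) 1240 against 73.8 (4.06 ± 0.31) and LEA14 (AT1G01470) 510 against 121 (2.07 ± 0.17). SAG21 (0.5), ECP31 (1.21), M17 (0.35) and M10 (0.06) did not pass at 4 h. Of 25 measured 21 passed, 21 when adjusted over the list alone and 21 with paired blocks (camera adjusted p = 2.26e-22, adjusted p = 0.0345 with an estimated correlation). Of 16 seed genes 3 were called at 4 h and 6 at 8 h. At 36 h the oil body genes OLEO5 (AT3G01570) by 4.74 ± 0.65, OLEO4 (AT3G27660) by 3.42 ± 0.44, CLO2 (AT5G55240) by 3.12 ± 0.29 (12.1 against 0.502 RPKM, adjusted p = 3.52e-07) and CLO1 (AT4G26740) by 2.27 ± 0.32 were higher. CRU2 (1.71), SESA4 (1.83) and OLEO3 (0.17) did not pass. In this list 13 of 16 were called at 36 h, 15 when adjusted over the list alone and 15 with paired blocks (camera adjusted p = 2.47e-11, adjusted p = 0.103 with an estimated correlation). The count falls to 7 without mock replicate 2 of 36 h and to 8 without ABA replicate 1; CRA1 alone had 10.9 RPKM in the former library and 199 in the other mock library.

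Suberin genes rose strongly at 4 h. ABCG6 (AT5G13580, chromosome 5, 4370692 to 4373201), for a transporter of suberin precursors, rose by 5.9 ± 0.22 (67.6 against 0.145 RPKM, adjusted p = 1.6e-12), GPAT5 (AT3G11430, chromosome 3, 3595694 to 3597952) by 5.1 ± 0.17 (34.8 against 0.043), the regulator MYB41 (AT4G28110) by 4.4 ± 0.22 and CYP86B1 (AT5G23190) by 3.74 ± 0.15. MYB41 had 870 reads with ABA against 0 in mock, at least 308-fold against a floor of 3 reads. CYP86A1 (0.15), FAR1 (-0.08) and KCS20 (0.47) did not pass. Thus 10 of 13 were higher, 10 when adjusted over the list alone and 11 with paired blocks, with a median of 3.1 (camera adjusted p = 4.29e-20, adjusted p = 0.00112 with an estimated correlation). In the wax and lipid transfer list WSD1 (AT5G37300) rose by 3.82 ± 0.25 at 4 h and CER3 (AT5G57800) by 1.14 ± 0.12, beside LTP3 and LTP4; LTP2 (0.55) and CER4 (0.92) did not pass. This was 12 of 14, 14 when adjusted over the list alone and 13 with paired blocks (camera adjusted p = 1.12e-16, adjusted p = 0.0198 with an estimated correlation). In the Casparian strip list at 60 h CASP4 (AT5G06200) fell by 1.35 ± 0.23 (18.4 against 48.3 RPKM, adjusted p = 0.000398), and ESB1 (AT2G28670, -1.33 ± 0.25) was lower. CASP1 (-1.19) and MYB36 (-0.61) were among those that did not pass, and 3 of 9 did, 6 when adjusted over the list alone and 8 with paired blocks (camera adjusted p = 0.000141, adjusted p = 0.276 with an estimated correlation).

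Of 21 aquaporin genes 5 were higher at 4 h, 7 when adjusted over the list alone and 8 with paired blocks, the seed-type genes TIP3;1 (2.39) and TIP3;2 (1.3) among them (camera adjusted p = 0.00263, adjusted p = 0.288 with an estimated correlation). At 4 h TIP2;3 (AT5G47450) rose by 1.32 ± 0.2 (741 against 294 RPKM), and at 36 h it fell by 1.13 ± 0.2 (210 against 464). PIP2;3 (AT2G37180, chromosome 2, 15617635 to 15619155), for a plasma membrane water channel, fell by 2.46 ± 0.24 at 36 h (17.9 against 103 RPKM, adjusted p = 6.9e-07) and TIP1;1 (AT2G36830) was lower (-1.06 ± 0.18), while TIP3;1 (AT1G73190) rose by 4.15 ± 0.58. At 36 h 2 of 21 were higher and 12 lower, 3 and 13 when adjusted over the list alone and 3 and 12 with paired blocks (camera adjusted p = 1.9e-05, adjusted p = 0.123 with an estimated correlation); PIP1;1 (-0.35), PIP1;2 (-0.39) and TIP1;2 (-0.6) did not pass. At 60 h 2 were higher and 8 lower, 4 and 12 when adjusted over the list alone and 3 and 12 with paired blocks (camera adjusted p = 0.000911, adjusted p = 0.247 with an estimated correlation). At 8 h the median of this list was -0.11 and its mean 0.17. Some cytokinin response regulators were lower at 60 h: ARR7 (AT1G19050, -1.95 ± 0.29), ARR6 (AT5G62920, -1.72 ± 0.25), ARR5 (AT3G48100, -1.67 ± 0.24, 8.99 against 31 RPKM, adjusted p = 6.9e-05) and ARR4 (AT1G10470, -1.01 ± 0.22, lost in 2 leave-one-out fits); ARR3 (-0.1), ARR8 (-0.36), ARR9 (-0.04) and ARR16 (-0.58) did not pass. That is 4 of 8 measured, 4 when adjusted over the list alone and 6 with paired blocks (camera adjusted p = 0.000228, adjusted p = 0.0729 with an estimated correlation).

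In growth-related lists the counts depend on pairing. Some cell cycle genes were lower at 8 h, with CDKB2;2 (AT1G20930, -0.6 ± 0.14) and TSO2 (AT3G27060, -0.59 ± 0.16) among 6 of 19 called, 10 when adjusted over the list alone and 15 with paired blocks; PCNA1 (-0.7) and MCM2 (-0.45) did not pass (camera adjusted p = 7.58e-07, adjusted p = 0.264 with an estimated correlation). Auxin genes were lower at 12 h in 4 of 19 cases, 7 when adjusted over the list alone and 9 with paired blocks, with SAUR15 (AT4G38850, -1.22 ± 0.26) and IAA1 (AT4G14560, -0.96 ± 0.28), while IAA19 (-0.61) did not pass (camera adjusted p = 0.000985, adjusted p = 0.404 with an estimated correlation). In the cell wall list at 60 h XTH16 (AT3G23730) was higher by 1.07 ± 0.23 and XTH4 (AT2G06850) and EXPA10 (AT1G26770) lower by -0.95 and -0.85; 1 higher and 2 lower of 20 was the count both ways, over all genes and adjusted over the list alone, and 4 higher and 5 lower with paired blocks (camera adjusted p = 0.876). Its median there was -0.02 and its mean 0.02. XTH14 (AT4G25820) was the single root hair marker of 10 called at 60 h, with 1.2 ± 0.39 (adjusted p = 0.0471, and lost in 3 leave-one-out fits, with a pseudocount of 5 and with voom weights); adjusted over the list alone it did not pass, and paired blocks gave 1 higher and 1 lower (camera adjusted p = 0.924). This list's median was -0.05 and its mean 0.08. Stomatal and guard cell markers at 4 h had 2 higher and 1 lower of 9, 2 and 1 when adjusted over the list alone and 2 and 2 with paired blocks: the channel genes ALMT12 (AT4G17970) by 1.57 ± 0.19 and GORK (AT5G37500) by 1.42 ± 0.15, and EPF1 (AT2G20875) by -0.71 ± 0.2. The median was -0.18, the mean 0.08 and the camera direction up (adjusted p = 0.994). In the gibberellin list GASA1 (AT1G75750) by 1.64 ± 0.38 and GA20OX2 (AT5G51810) by 0.93 ± 0.27 were the 2 of 10 higher at 36 h, 2 when adjusted over the list alone, and paired blocks gave 2 higher and 1 lower, with a median of -0.09, a mean of 0.09 and camera up (adjusted p = 0.887); GA20OX1 (-0.94) did not pass. Brassinosteroid genes BAS1 (AT2G26710) and DWF4 (AT3G50660) were the 2 of 6 lower at 36 h, by -0.91 ± 0.13 and -0.63 ± 0.19, 2 when adjusted over the list alone and 3 with paired blocks (camera adjusted p = 0.0542); CPD (-0.52) did not pass. Of the genes named here as changed, ALMT12, GORK and BAS1 kept their call without any of the 4 libraries of the time, and the others did not.

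At 24 h the RuBisCO small subunit genes RBCS1B (AT5G38430) by -2.4 ± 0.38 (9.55 against 54.2 RPKM, adjusted p = 0.000247), RBCS3B (AT5G38410) by -1 and RBCS2B (AT5G38420) by -0.96 were the 3 of 22 called in the light harvesting list, 4 when adjusted over the list alone and 8 with paired blocks, while LHCB1.2 (-1.63) did not pass (camera adjusted p = 0.000425, adjusted p = 0.4 with an estimated correlation). PIF3 (AT1G09530) was higher at 4 h by 0.63 ± 0.16, as 1 of 13 chlorophyll and dark-growth genes, 1 when adjusted over the list alone and 2 with paired blocks; PIF4 (0.62) and HY5 (-0.32) did not pass, the list's median was -0.03 and its mean 0.08 (camera adjusted p = 0.887). Of 12 clock genes RVE8 (AT3G09600), ELF4 (AT2G40080) and CCA1 (AT2G46830) were higher at 12 h, by 1.21 ± 0.25, 1.58 ± 0.39 and 0.87 ± 0.25, which makes 3, and 3 higher and 1 lower when adjusted over the list alone, 4 and 2 with paired blocks; TOC1 (-0.06) did not pass (camera adjusted p = 0.566). Senescence genes were higher at 4 h in 6 of 11 cases, 6 when adjusted over the list alone, and paired blocks gave 8 higher and 1 lower, with SAG29 (AT5G13170) by 4.17 ± 0.27 and SGR2 (AT4G11910) by 1.77 ± 0.29; ASN1 (0.19) did not pass (camera adjusted p = 9.2e-05, adjusted p = 0.0859 with an estimated correlation). Jasmonate genes VSP1 (AT5G24780), JAZ1 (AT1G19180) and VSP2 (AT5G24770) were higher at 60 h by 2.68 ± 0.33, 1.86 ± 0.26 and 1.36 ± 0.32, 3 of 7, 4 when adjusted over the list alone and 4 with paired blocks, while JAZ10 (0.01) did not pass (camera adjusted p = 0.0285, adjusted p = 0.0763 with an estimated correlation). The flavonoid genes CHI (AT3G55120) and F3H (AT3G51240) were higher at 12 h by 1.23 ± 0.29 and 1.2 ± 0.36, 2 of 10, 3 when adjusted over the list alone and 4 with paired blocks; CHS (-0.08) did not pass (camera adjusted p = 0.141). Among 7 hypoxia genes PDC1 (AT4G33070) was higher at 4 h by 1.09 ± 0.18 and HRE1 (AT1G72360) lower by -1.05 ± 0.14, 2 higher and 1 lower when adjusted over the list alone and with paired blocks; SUS4 (0.45) did not pass (camera adjusted p = 0.47). RBCS2B, RBCS3B, PIF3, ELF4, CCA1, VSP2, CHI and F3H lose their call in some leave-one-out fits. Over all lists and times 113 of 210 camera tests passed and 55 held with an estimated correlation. By fry's directional p 99 of the 113 passed.

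How does the ABA effect differ between times? The ABA effect on PELPK1, GPAT5 and the lipase-type gene AT3G50400 was smaller at 60 h than at 4 h (60 h minus 4 h -2.5 ± 0.26, -1.98 ± 0.25 and -2.39 ± 0.28). For PELPK1 mock seedlings went from 0.491 to 5.31 RPKM between these times (adjusted p of the mock course = 7.91e-07) and ABA seedlings from 195 to 146. PELPK1, GPAT5 and AT3G50400 had the smallest p of the test for a time-dependent effect (adjusted p = 2.65e-10, 1.57e-07 and 1.32e-07). AT1G29090 (1.57e-07) and PGAZAT (1.6e-07) stood beside them. None of these 5 genes was called at 1 h, where their differences were 0.26, 0.49, 0.19, -0.25 and 0.47 in this order. At 4 h they were 7.03, 5.1, 5.64, -4.09 and -3.37. For AT1G29090 (-0.14) and PGAZAT (-0.29) the 60 h minus 4 h difference did not pass (adjusted p = 0.968 and 0.86). From 4 h to 60 h the effect grew for the seed storage gene PAP85 (AT3G22640, chromosome 3, 8011724 to 8013941) by 4.64 ± 1.02 (adjusted p = 0.0172; 233 against 8.19 RPKM at 60 h, 14.9 against 13.6 at 4 h), for AZI1 (AT4G12470), of systemic immunity, by 3.88 ± 0.48 and for XTH25 (AT5G57550), a xyloglucan endotransglucosylase gene, by 3.55 ± 0.49. AZI1 was lower with ABA at 4 h (-2.07) and higher at 60 h (1.81). The decrease with ABA became larger for AIR1, from -1.11 to -6.32 (60 h minus 4 h -5.21 ± 1.2, adjusted p = 0.0233). It also became larger for AT5G64110, from -0.45 to -4.28 (-3.82 ± 0.43). Neither gene passed at 4 h. AT4G37220, of the WCOR413 cold-acclimation family, went from higher with ABA (1.47) to lower (-2.26, a change of -3.73 ± 0.45). Its ABA values changed little between 4 h and 60 h (125 and 158 RPKM), while mock rose from 45 to 761 RPKM. AIR1 and PAP85 lose this call in some leave-one-out fits. NCED3 was lower in the 60 h minus 4 h contrast too (-1.89 ± 0.29, adjusted p = 0.00102). In log2(RPKM + 1) its mock libraries rose from 1.98 and 1.682 to 2.794 and 2.385, and its ABA libraries fell from 3.689 and 3.618 to 2.685 and 2.352. Lower in this contrast were also 7 of 13 suberin genes, 10 with paired blocks (camera adjusted p = 3.11e-10, adjusted p = 0.0263 with an estimated correlation). An ABA effect at any time was found in 4315 genes (23.6%; 8600 with paired blocks) and one that differs between times in 764 (4.2%; 2609). For 60 h minus 4 h 451 genes passed (134 up, 317 down; 2106 paired), and for 4 h minus 1 h 416 (357 up, 59 down; 1302 paired). Without a single library the last 3 counts fall as low as 504, 240 and 237.

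**Figure D4:**
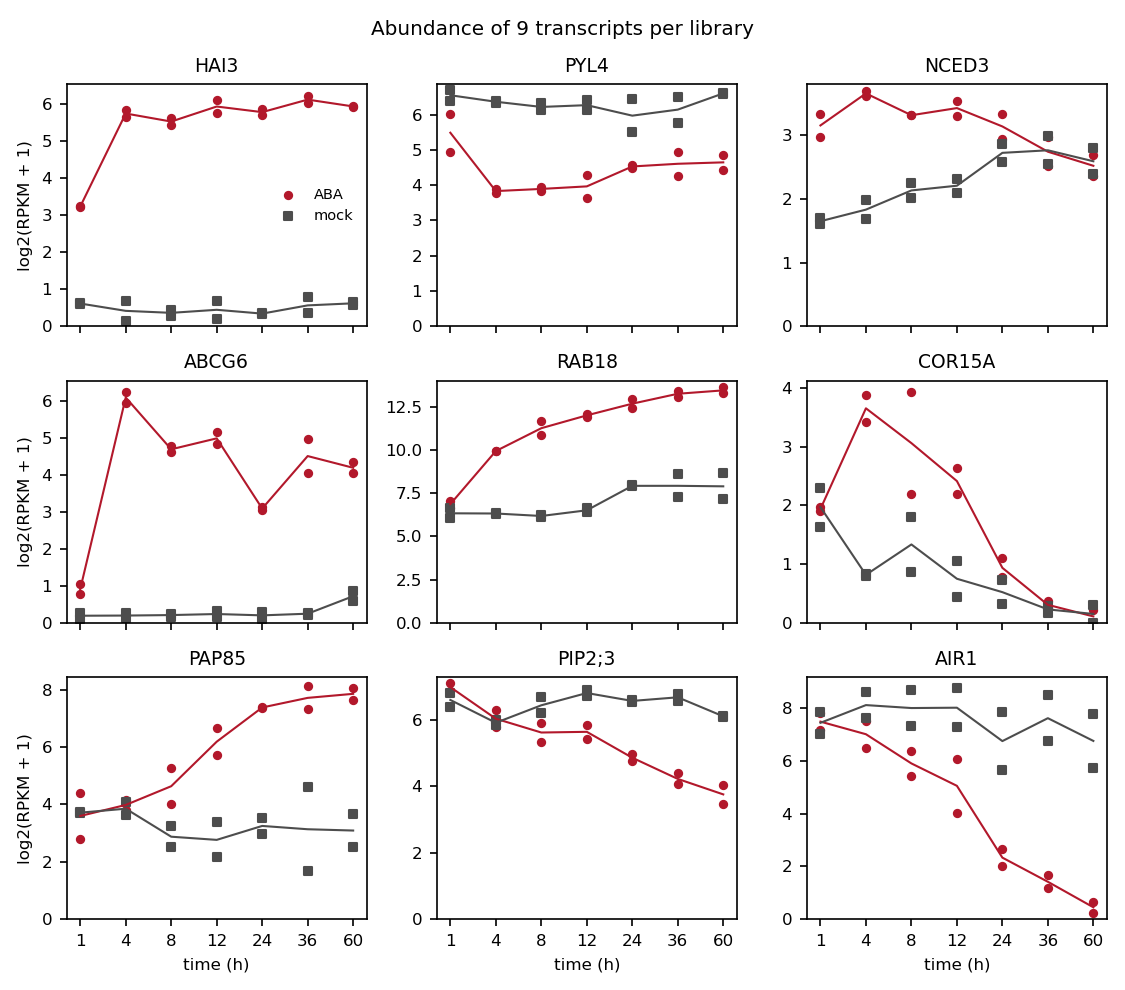
Values per library of 9 genes over time, with and without ABA, among them NCED3 (1.82 at 4 h, -0.07 at 60 h) and PIP2;3 (-2.46 at 36 h). Lines join the means of 2 libraries.

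Mock seedlings changed over the 60 h as well. The genes with the smallest p were NdhN (AT5G58260), of the chloroplast NDH complex, from 38.9 to 3.37 RPKM between 1 h and 60 h (adjusted p = 3.49e-09), and EBP (AT3G16770), an ERF-type factor, from 17.6 to 775 RPKM. AT4G08360 rose from 0.295 to 11.4, AT4G28740 fell from 18.7 to 2.92 and AT5G16350 from 5.43 to 0.5 RPKM (adjusted p = 7.51e-09 for each of these and EBP). In this test 10067 genes passed, 55% of the table, or 12339 with a block for replicate number. Age, medium and time of day all change along this course, so it has no reference group.

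The authors' deposited calls came from the same libraries and are no independent test. At an FDR under 0.05 they held 491, 2318, 2090, 2287, 1960, 2498 and 2434 genes in order of time. Of the limma calls 94.5% at 1 h (362 genes) and 88.4% at 60 h (2196 genes) were among them with the same sign, and the shares in between lay in that range. Log2 differences of the authors and of the model correlated across genes with Pearson's r between 0.883 and 0.931. Differences for genes of low RPKM are smaller here, because 1 was added before the logarithm: HSFA6B at 1 h is 5.97 in the authors' column and 4.83 here.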

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

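Of the tests in this part, those on seed tissue, the storage protein ratio included, on the scaling of oleosin genes and on whether root-restricted genes moved alike were chosen only after the result was seen.

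A difference of the ABA effect between times singled out 764 genes by the moderated F test over 7 times, 451 genes between 60 h and 4 h, and 416 between 4 h and 1 h; leaving out a library lowers these counts to as few as 504, 240 and 237. The smallest adjusted p of the F test belonged to PELPK1 (2.65e-10), AT3G50400 (1.32e-07), AT1G29090 (1.57e-07), GPAT5 (1.57e-07) and PGAZAT (1.6e-07). For 60 h minus 4 h the largest called differences were PAP85 (4.64), AZI1 (3.88) and XTH25 (3.55) upward, and AIR1 (-5.21), AT5G64110 (-3.82) and AT4G37220 (-3.73) downward. PAP85 loses its call without mock 4 h replicate 1 (adjusted p = 0.0795), mock 4 h replicate 2 (0.051), ABA 4 h replicate 1 (0.0814), mock 60 h replicate 2 (0.0852) or ABA 60 h replicate 1 (0.0647), with 0.00238 the lowest value over the leave-one-out fits. AIR1 loses its call without mock 4 h replicate 2 (adjusted p = 0.122), ABA 4 h replicate 1 (0.118), mock 60 h replicate 1 (0.141), ABA 60 h replicate 1 (0.0754) or ABA 60 h replicate 2 (0.0543), with a pseudocount of 5 (0.157) and with voom weights (0.282), against 0.00538 with a pseudocount of 0.1. The other genes named here kept theirs in the leave-one-out fits.

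A chance swap of labels within pairs seldom gives the count of the mean over times, as far as 100 splits can show. Whether pairs were separate cultures is not stated, so this holds for the labels of these libraries only. In 100 of 8192 splits that part the libraries of each pair, 1 gave as many genes, the real split itself with 7165. The highest other count was 5487, from a split with 2 of 14 pairs swapped, and the median of the others was 0. Swapping 1 of the 2 pairs of a time mixes ABA and mock libraries within a group, so any ABA effect adds to the spread. The low counts of other splits thus do not estimate how many of the 7165 calls are false.

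At 60 h 3 of 9 Casparian strip genes and 8 of 21 aquaporins were lower with ABA, while TIP3;1 (3.74) and TIP3;2 (1.86) were higher, and neither list passed with an estimated correlation (adjusted p = 0.276 and 0.247). The decreases did not depend on the choice among 3 scalings, since 11 of 11 members called lower kept that call under both other scalings. Their median was -1.1 against -1.08 as deposited. The other scalings moved the median over all genes at 60 h little (-0.018 and -0.039, against 0.002 as deposited). An error common to all 3 scalings was not tested. A lower share of root tissue in the ABA seedlings may contribute: 5 root-restricted genes with at least 1 RPKM in mock had a median of -2.01 (SE 0.85; 3 called lower; camera p = 6.99e-06, p = 0.0109 with an estimated correlation), below the bound of -0.58 that was set before these genes' values were seen, from the Casparian median of -1.16. As the whole cause, alike for every root gene, it is excluded, since SULTR1;2 (0.29) and PHT1;1 (-3.45) lay 3.75 apart (SE 0.34). Of 16 listed genes 9 were measured, 4 of them under 1 RPKM and left out (PLT1 -0.69 and SMB -0.69, both called lower, NRT2.1 0.2, FRO2 0.14). The others were FIT (-2.16), PHO1 (-2.01, at 50 RPKM in mock the most abundant) and PHT1;4 (-0.28). The limit of 1 RPKM was applied to mock alone, which favours falls with ABA. Root hair markers, described above, were not lower as a list at 60 h by camera, so a lower root share stays uncertain. No other biological explanation was tested.

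Of 5 oleosin genes 4 rose with ABA by 8 h (not OLEO3, 0.68), and 6 of 8 storage protein genes were higher at 36 h (not CRU2, 1.71, and SESA4, 1.83), when the seed list did not pass with an estimated correlation (adjusted p = 0.103). The rise of these 4 oleosin genes held under all 3 scalings, with a smallest rise of 2.21 (SE 0.45). The other scalings moved the median over all genes at 8 h little (-0.016 and -0.059, against 0.006 as deposited), so they could hardly have removed it. An error common to all 3 was not tested. Seed tissue left in the ABA samples and a response to ABA cannot be told apart at 8 h: the oleosin median (2.56) exceeded that of storage proteins (0.32) by 2.24 (SE 0.78), short of its bound of 1 by 2 SE, where a first run without OLEO3 gave 2.71 (SE 0.6), and the larger gain of oleosins in RPKM (318 against 79.8, a difference of 238 with SE 55.6) would decide only with a seed profile, which was not measured. Nor can they for storage proteins at 36 h: the log2 ratio of CRA1 to the SESA median (SD 1.18 over 12 libraries of 24 to 60 h) was higher with ABA in 5 of 6 pairs (3.69 to 4.63, against 1.49 to 4.27 in mock), but seeds added to the seedlings' own transcripts would shift it too. Of 16 seed genes 13 were called at 36 h, 7 without mock replicate 2 (where CRA1 had 10.9 RPKM against 199 in replicate 1), 8 without ABA replicate 1, 15 without ABA replicate 2 and 12 without mock replicate 1; no biological explanation was tested for this pattern.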

How the results depend on the processing

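Precision weights from voom on the recovered reads and the tests made with them were chosen only after the result was seen; the other settings were fixed before the data were examined. The tests on counts that had been planned were not run: whole reads were recovered and the tools were installed, but the instructions for this work keep count tools from tables in RPKM. Where a library is left out, the lone sample of its group is assumed to vary like the other groups. The cause was not tested, unless the setting's own construction shows it.

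Total counts stayed within 1.5 times those reported with pseudocounts of 0.1 and 5, the 1 RPKM filter, median-ratio scaling and quantile normalization. The same held, where each applies, with no intensity trend, voom weights and the authors' FDR. By direction, voom weights moved 60 h minus 4 h further, to 81 up and 241 down from 134 and 317. Scaling moved the split of directions: quantile normalization gave 40.3% higher for the mean over times (3190 higher, 4734 lower; 53.7% as deposited), 60.5% at 4 h (1485 and 970; 70.6%) and 56.1% at 12 h (1410 and 1102; 67.2%). The median over genes at a single time lay furthest from 0 at 4 h with quantile normalization (-0.091; -0.019 as deposited). Of 210 list medians 7 changed sign between scalings, each at most 0.1 in size as deposited: brassinosteroid and cell wall genes at 4 h, Casparian strip and photosystem genes at 8 h, cell wall genes at 1 h, gibberellin genes at 12 h and SnRK2 kinases at 60 h.

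A block for replicate number raised 1 h to 647, 12 h to 3498, 24 h to 2908, 60 h minus 4 h to 1060, 4 h minus 1 h to 765 and the time-dependent effect to 1455. A block per pair gave 901, 4996, 4578, 5208, 4473, 5443 and 5233 in order of time, 2106 for 60 h minus 4 h, 1302 for 4 h minus 1 h, 8600 at any time and 2609 for the time-dependent effect. An absolute log2 of at least 1 left 233, 1111, 1012, 1112, 916, 1182 and 1144 in order of time and 878 for the mean, fewer by construction. With only the 4 libraries of the time, 24 h gave 842, 36 h 1241 and 60 h 921, with fewer samples behind the spread.

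Leave-one-out counts ran from 211 to 291 at 1 h, 1420 to 1830 at 4 h, 1391 to 1818 at 8 h, 1507 to 1773 at 12 h, 1228 to 1412 at 24 h, 1680 to 1961 at 36 h and 1768 to 1964 at 60 h. They ran from 6765 to 7194 for the mean, 240 to 478 for 60 h minus 4 h, 237 to 458 for 4 h minus 1 h, 3851 to 4531 at any time, 504 to 753 for the time-dependent effect and 8811 to 10229 for the mock course. Moves beyond 1.5 times were: at 1 h without mock replicate 1 (211), mock replicate 2 (225) and ABA replicate 2 (221); at 4 h without mock replicate 2 (1527) and ABA replicate 1 (1420); at 8 h without ABA replicate 2 (1391). At 12 h this was so without mock replicate 2 (1507), at 24 h without ABA replicate 1 (1228) and at 36 h without mock replicate 2 (1680). For 60 h minus 4 h it was so without mock 4 h replicate 1 (291), mock 4 h replicate 2 (247), ABA 4 h replicate 1 (240) and mock 60 h replicate 1 (264). For 4 h minus 1 h the libraries were mock 1 h replicate 2 (263), mock 4 h replicate 1 (275) and ABA 4 h replicate 1 (237), and for the time-dependent effect mock 1 h replicate 2 (504).

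Of 210 list tests 113 passed with the preset correlation and 55 with an estimated correlation, which allows for members that move together. In the mean over times fry found the stomatal and guard cell list up (adjusted p = 0.00117) where camera gave down (0.563; 0.7 with an estimated correlation); fry tests members alone and camera against other genes.

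All 96 gene results named by rule kept direction and call under both scalings, a pseudocount of 0.1 and both blocks, 95 with a pseudocount of 5 and with voom weights, and 94 in leave-one-out fits. Of 1328 calls of list members 1314 were kept with median-ratio scaling, 1299 and 1293 with pseudocounts of 0.1 and 5, 1284 with quantile normalization, 1327 and 1328 with blocks per pair and for replicate number, and 1283 with voom weights. Of 2512 members that did not pass, 656 are called with a block per pair, 336 with a block for replicate number and 86 with quantile normalization, so such statements depend on the model. Of the 985 calls tested by leaving out libraries, 978 of them at single times, 674 held in each such fit. At 16.27 M reads, the lowest depth, 1 read is 0.041 RPKM at the median gene, so depth limits genes near that level. The rest are limited by 2 libraries per group. In a simulation with each gene's spread averaged over the 14 groups, the model recovered 1.5% of 1.5-fold, 40.3% of 2-fold and 87.9% of 4-fold changes. It called 87 genes at 4 h there, against 2329 in the data, so these shares need not hold for the data.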

Other observations

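The test of scaling for ELIP1 and ELIP2 was chosen only after the result was seen, and the genes themselves were chosen after their values were seen.

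ELIP1 and ELIP2, which encode early light-induced proteins of the chloroplast, were high at the start of treatment in both arms. In mock seedlings ELIP1 had 393 RPKM at 1 h and 15.9 at 4 h, and ELIP2 256 and 28.3; ELIP1 with ABA had 374 and 26.4. By 60 h ELIP1 stood at 1.88 RPKM and ELIP2 at 2.11 in mock. The fall held under all 3 scalings, with -3.14 (SE 0.68) the smallest over them. Median RPKM was alike in the mock libraries of 1 h (11.23 and 11.41) and 4 h (11.35 and 11.45), so these scalings could hardly have removed it. An error common to all 3 was not tested.

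Light that reached the seedlings around the start of treatment is a candidate explanation. Of 13 other light-induced genes, listed after the main results but before their own values were seen, 10 were measured, with a median mock change from 1 h to 4 h of -1.05 (SE 0.38; camera p = 1.81e-06, p = 0.00422 with an estimated correlation). Lower were RUP2 (-1.94), SIG5 (-1.56), HYH (-1.48), CRY3 (-1.39), SPA1 (-1.08) and PHR1 (-1.03), while SPA4 (-0.13), RUP1 (-0.15), BBX22 (0.52) and UVR3 (0.87) did not pass. The 7 dark-induced genes had a median of 0.5 (SE 0.37; 1 called higher, ST2A by 2.19; camera p = 0.00331, p = 0.18 with an estimated correlation), which is weak. Time of day stays open, since many of these genes follow the clock and the hours of sampling are not given.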
